A study of Mus musculus with 2 samples.

How the data were processed

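Chromatin bound by TBP, the TATA-binding protein of the general transcription machinery, was measured by ChIP-seq in V6.5 mouse embryonic stem cells, a line from a C57BL/6-129 cross. Both libraries used the Abcam antibody AB818 and belong to 1 group. B2 is called replicate 1 and B6 replicate 2; these numbers follow deposit order and only name the libraries. Per the labels' protocols, cells were taken off feeder fibroblasts for 2 passages before B2 and for 1 passage before B6, and the gel cut also differed slightly at its upper end. The labels do not say that the libraries came from separate cultures, and no library without the antibody was analysed here.

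The deposited files are lists of alignments: each line is a signed position on mouse build mm8, with the minus sign for the minus strand, and the values are other than counts per feature, per the file headers and the values themselves. Reads were aligned with Bowtie, per the file headers and the submitters' processing notes; its version is not given in the sources used here. The headers give the settings -e 70, -k 2, -m 2 and -n 2, with a seed (-l) of 36 for B2 and 26 for B6, so reads with more than 2 alignments had been dropped by the authors. Reads with 1 alignment and reads with 2 were listed apart. On chromosome M the highest position plus the read length reached 16299 in both libraries, which checked the read lengths of 36 and 26 bases and the reading of a position as the leftmost base.

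Everything after alignment was computed from these positions with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. Reads with 1 alignment on chromosomes 1 to 19, X and Y were reduced to 1 read per position and strand ("distinct reads"). Each 5 prime end was moved 60 bp towards the fragment centre, and reads were counted in windows of 200 bp every 50 bp. A one-sided Poisson test compared each window with the highest of the genome-wide rate and the local rates in 5 kb and 10 kb. Windows with p at most 1e-09 and at least 20% of reads on each strand were kept, and touching windows were merged into regions. Rates and densities used the mapped length, 2266 Mb of 1-kb bins that held reads.

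Regions were compared between libraries by overlap of at least 1 bp, against 1000 random circular shifts along each chromosome. Pearson's r and Spearman's rho were taken over log2 of RPM (distinct reads normalised to the library's total) plus 0.5. A two-sided exact binomial test compared the distinct reads of each region with the B6 share found in the regions called in both libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. B2 was also thinned at random to the read number of B6. Regions per chromosome were set against protein-coding genes per chromosome with 100000 permutations. Intervals are 95% and cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

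The gene table at hand belongs to another assembly, GRCm38.p6, so it served only for gene numbers per chromosome, and no coordinate was taken from it or converted. The planned test of occupancy at gene promoters, with its fixed gene lists, needs an annotation of mm8 and was not run. Regions are therefore named by position. The rule, fixed before the data were examined, took the 10 regions called in both libraries with the highest mean RPM in their highest window, the 3 widest, the highest on each sex chromosome, and the 3 with the largest difference in each direction among those past the threshold. Other settings tried were all reads kept, other p thresholds, windows, shifts and background rates, other pseudocounts and reads with 1 or 2 alignments.

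The procedure was tested on simulated libraries. With nothing planted, 2 regions were called at the depth of each library. Each read had been moved at random within its bin of 10 kb, so false calls from narrower pile-ups of background were not measured. Of 50 planted sites per size, 2% were found in B2 at 5-fold, 40% at 10-fold and 100% at 20-fold over the mean window. At the depth of B6, 0% were found at 20-fold and 46% at 40-fold, so a weak site missed in B6 is not shown to be absent. The test of read shares recovered 92% of 200 planted 4-fold increases in B6, with 9 false calls over 13097 regions. Decreases in B6 were not planted, so the power to find them was not measured. The simulated reads had binomial spread only, so false calls from any wider spread between libraries were not measured either.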

Results

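TBP occupancy was profiled in V6.5 mouse embryonic stem cells with 2 libraries of 1 group. B2 (replicate 1) held 16848742 reads with 1 alignment and B6 (replicate 2) held 3106240. After removal of duplicates, 15887305 and 2856259 distinct nuclear reads remained, and duplicates made up 5.61% and 7.86% of the nuclear reads. A window of 200 bp held on average 1.40 distinct reads in B2 and 0.252 in B6. With 1 group, the comparison that the design implies is whether both libraries mark the same places. P-values below measure these 2 libraries and chance placement. The labels give different passages off feeders for the libraries but do not say that the cultures were separate.

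Reads were enriched in short regions that both libraries shared. No control library was analysed, so binding by TBP was not separated from other repeatable pile-ups of reads. B2 gave 12812 enriched regions with a median width of 350 bp, and B6 gave 6808 with a median width of 300 bp. Of the B6 regions, 6518 (95.7%, Wilson 95% interval 95.2 to 96.2) overlapped a B2 region. Random circular shifts gave a mean of 25.8 overlapping regions and at most 42 (permutation p = 0.000999, the smallest that 1000 shifts can give). Seen from B2, 6449 regions (50.3%) overlapped a B6 region. The merged set held 13097 regions, of which 6444 were called in both libraries, 6363 in B2 alone and 290 in B6 alone. The shared regions covered 0.132% of the mapped length and held 4.28% of the distinct reads of B2 and 8.78% of those of B6. These shares were 32.5-fold and 66.8-fold over a uniform spread. With duplicates kept, the shares were 5.68% in B2 and 9.89% in B6, so the contrast between libraries was smaller. Shared regions also had to pass in B6, which held fewer reads, and this can favour high B6 counts.

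Reads in the shared regions were offset between the strands. The median distance from plus-strand to minus-strand ends was 94 bp in B2 and 93.5 bp in B6, and it was above 0 in 98.9% and 98.1% of regions. Part of this offset can be built in, because ends were moved 60 bp before regions were called and centred. Without called regions, plus and minus ends of distinct reads coincided most at 95 bp in B2 and 73 bp in B6. That search left out short distances. Mean profiles, in RPM (distinct reads normalised to the library's total of distinct reads) per kb, rose to 14.04 on the plus strand in B2 and to 32.4 in B6.

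**Figure D1:**
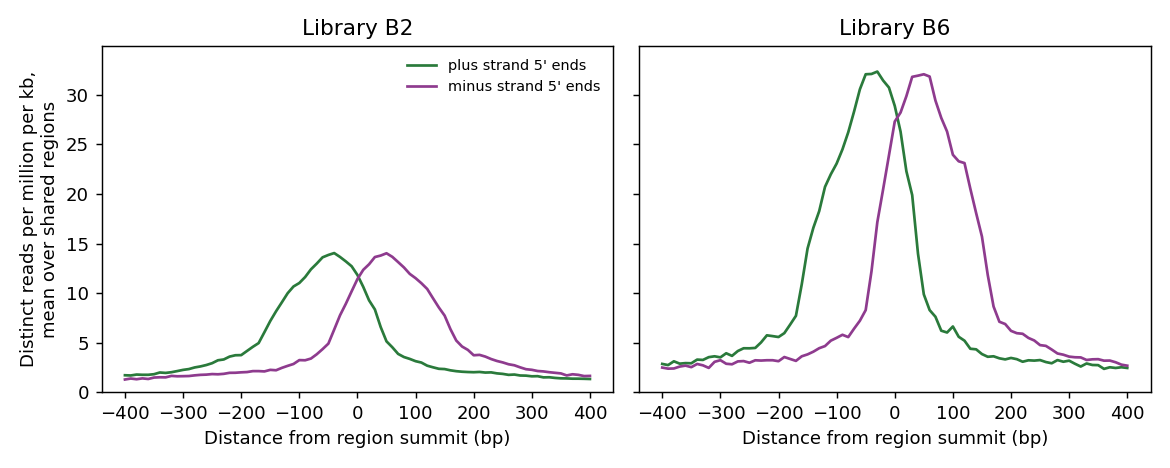
Mean distinct 5 prime ends in RPM per kb (vertical axis) by distance from the region summit in bp (horizontal axis) in regions called in both libraries, with plus-strand ends in green and minus-strand ends in purple, for B2 (left) and B6 (right). Plus-strand ends peak before the summit and minus-strand ends after it, with peaks of 14.04 in B2 and 32.4 in B6 on the plus strand.

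The densest signal lay on chromosome 17 between 39451201 and 39456950, where 5 of the 10 highest shared regions stood. Over these 5750 bp, reads occupied 66.0% of the possible positions in B2 and 62.7% in B6. The 5 regions may therefore be parts of 1 continuous stretch rather than separate sites. The strongest, from 39451801 to 39453000, held 14640 reads of B2 and 9027 of B6 before removal of duplicates, and 2249 and 2182 distinct reads after it. Its highest window held 398 distinct reads in each library out of 400 possible, so distinct reads no longer measured its height. The next highest region by the mean of both libraries lay on chromosome 11 from 108827651 to 108828250, with 456 distinct reads in B2 and 454 in B6. Its summit reached 96.98 RPM in B6 but 16.99 in B2, below the B2 summits of the 4 regions named next. With duplicates kept it held 2837 reads in B2, more than those 4, whose highest count was 2514. The other four of the 10 were on chromosome 11 at 75326801 to 75327350 (444 and 251 distinct reads), on chromosome 9 at 123774151 to 123774650 (340 and 180), on chromosome 11 at 106828651 to 106829200 (438 and 180) and on chromosome 11 at 58118251 to 58119050 (720 and 304). For comparison, the median shared region reached 3.65 RPM in its highest window in B2 and 7.70 in B6. The summit of the region at 75326801 reached 20.6 and 77.4 RPM, a mean of 49.0 ± 40.2 (SD, n = 2). The widest shared region lay on chromosome 1 from 172938401 to 172939900 and held 997 and 395 distinct reads. Next came chromosome 3 from 19820001 to 19821350 (1120 and 348) and chromosome 5 from 3000051 to 3001400 (776 and 389). On chromosome X the highest shared region was 165331001 to 165331400, with 180 and 112 distinct reads. Chromosome Y had 1 shared region, from 1780751 to 1781150, with 46 and 17.

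Regions called in a single library also held reads of the other. In the 6363 regions called in B2 alone, B6 had 13.3-fold more distinct reads than expected from the flanks (interval 13.2 to 13.4), and 98.98% of these regions lay above their flanks. In the 290 regions called in B6 alone, B2 had 6.50-fold more (6.33 to 6.67), and 100% lay above their flanks. Duplicates made up 29.0% of the B6 reads in those 290 regions, against 18.2% in shared regions. In the regions called in B2 alone, duplicates made up 10.5% of the B2 reads, against 28.96% in shared regions. Across the 13097 regions, log2 RPM correlated between libraries with r = 0.852 and rho = 0.860. Over 236603 bins of 10 kb outside the regions, r was 0.833 and rho 0.810. These are correlations across regions and bins, which are not independent replicates.

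**Figure D2:**
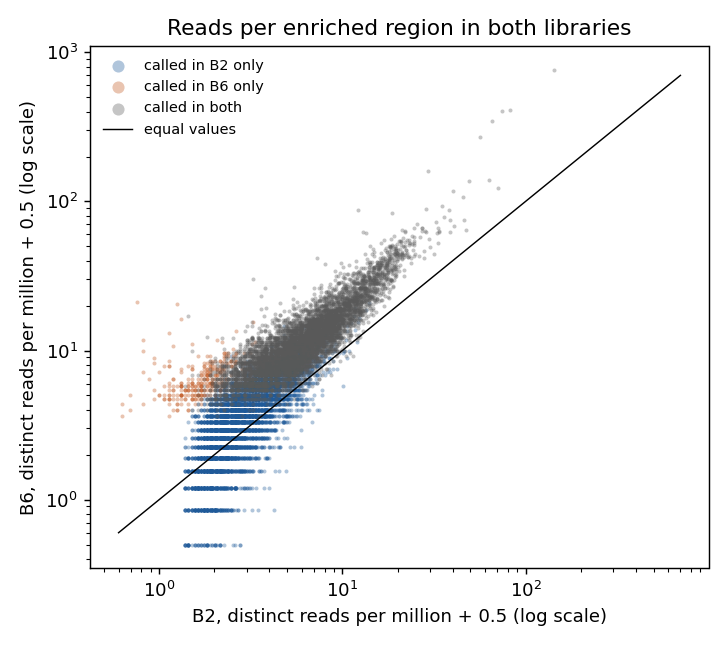
Distinct reads in RPM plus 0.5 in B2 (horizontal, log scale) and B6 (vertical, log scale), with 1 point for each of the 13097 regions: 6444 called in both libraries (grey), 6363 in B2 alone (blue) and 290 in B6 alone (orange). Most grey points lie above the line of equal values. The share of distinct reads in shared regions was 2.05-fold larger in B6, and with duplicates kept the shares were 5.68% in B2 and 9.89% in B6.

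Few regions passed the test for a different share of reads between the libraries. Power was measured only for 4-fold increases in B6, so a region that did not pass may still differ. Of 13097 regions, 420 (3.21%) passed the exact binomial test at an adjusted p of 0.05, with 165 higher and 255 lower in B6. Of these, 202 lay in regions called in B2 alone, and among the 6444 shared regions tested on their own 123 differed, 82 higher and 41 lower in B6. By distinct reads, the highest relative ratio of B6 was on chromosome 13 from 9010901 to 9011200, with 4 in B2 and 59 in B6, a ratio of 39.98 (interval 14.8 to 151.6). Chromosome 5 from 109839251 to 109839500 (5 and 32, ratio 17.4) and chromosome 11 from 46519201 to 46519500 (5 and 27, ratio 14.6) followed. With duplicates kept, these regions held 38 and 284, 102 and 433, and 5 and 64 reads, so their order depends on the treatment of duplicates. The regions with the largest difference in the other direction had 0 reads in B6. These lay on chromosome 4 from 134850651 to 134850950 and on chromosome 6 from 122730751 to 122730950, each with 36 distinct reads in B2, where the interval of the relative ratio reached up to 0.293. The third was on chromosome 1 from 84572001 to 84572350, with 33 reads and an upper bound of 0.321. Each region named here, in either direction, was called in only 1 library. The high count that selected it therefore also entered its ratio and interval. With the expected share taken from all distinct reads, 5712 regions differed, 5697 higher and 15 lower in B6, so the split depends on the scaling and on the regions tested. With all reads kept, 924 differed (403 higher, 521 lower).

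At an equal number of distinct reads, more regions were called in B6 than in B2. B2 thinned to 2856259 distinct reads gave 2585 regions against 6808 in B6, a ratio of 2.63. Of the 2585, 2396 (92.7%) overlapped a B6 region. Thinning before removal of duplicates gave 3249 regions, and the read lengths of 36 and 26 bases were not matched.

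Chromosomes with more genes carried more shared regions. Chromosome 11 had the highest density among autosomes, 558 regions or 4.96 per mapped Mb, and chromosome 14 the lowest, 207 or 2.01 per Mb. The autosomal median was 3.10 per Mb. Chromosome X held 119 regions, or 1.09 per Mb, where its background reads per Mb were 0.402 of the autosomal median in B2 and 0.423 in B6. Over 21 chromosomes, shared regions and annotated protein-coding genes correlated with r = 0.878 and rho = 0.907 (permutation p = 1e-05 for each, the smallest possible, adjusted p = 1.67e-05 over 5 relations). Without chromosomes 7 and 2, r was 0.898. Taken per mapped Mb, r was -0.410 (permutation p = 0.102) while rho was 0.553, and without chromosomes Y and 7 r was 0.832. Chromosome Y had 1.21 Mb mapped and 256 annotated genes.

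**Figure D3:**
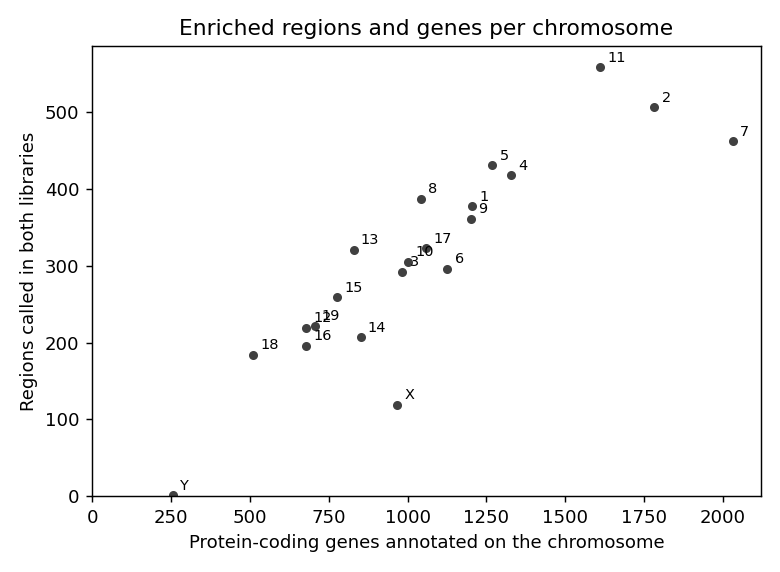
Number of regions called in both libraries (vertical axis) against annotated protein-coding genes (horizontal axis), with 1 labelled point per chromosome. Chromosome 11 has 558 regions and 1609 genes, while chromosome X has 119 regions and 966 genes.

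Shared regions lay close together more often than chance placement gave. Of the 6444, 969 (15.04%) had another within 10 kb, against a mean of 5.63% and a highest value of 6.84% in 1000 random draws (permutation p = 0.000999, the smallest possible). Runs of at least 10 shared regions with gaps of at most 50 kb numbered 14 and held 222 regions (3.45%); this definition was chosen after the data were seen. Chromosome 13 held 5 of these runs with 115 regions. The longest, from 23376451 to 23630250, held 43 regions with a median of 11.6 RPM in B2 and 22.4 in B6. The runs from 21862651 to 22058500 and from 21168101 to 21410350 held 28 and 23 regions. Chromosome 11 had a run of 17 regions from 68789951 to 68941700, with medians of 18.1 and 34.7 RPM, and chromosome 3 a run of 13 from 96484351 to 96587150. In the run on chromosome 9 from 2999951 to 3036550, the median distance between strands in B2 was 36 bp, the read length, against 67.3 to 124 bp in the other 13 runs. Without its runs chromosome 13 kept 206 shared regions, or 1.99 per Mb.

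**Figure D4:**
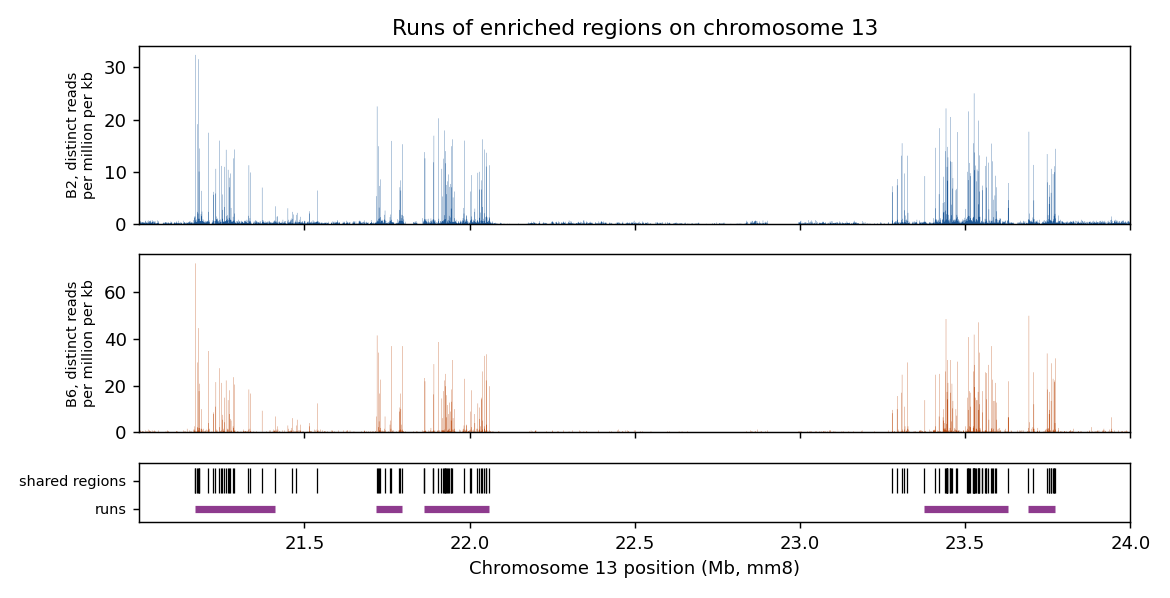
Distinct reads in RPM per kb (vertical axes) along chromosome 13 in Mb of build mm8 (horizontal axis) for B2 (blue) and B6 (orange), above ticks for shared regions and purple bars for runs. The 5 runs together hold 115 shared regions, and the longest, from 23376451 to 23630250, holds 43.

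Background reads outside regions were spread over chromosomes in much the same way in both libraries, with chromosome 8 apart from the other autosomes. There the ratio of B6 to B2 was 1.099 times the autosomal median, against 0.990 to 1.03 on the other 18 autosomes, 1.06 on X and 1.23 on Y. All 27 bins of 5 Mb on chromosome 8 lay above the median, from 1.02 to 1.18 times, against 47.1% of bins on the other autosomes.

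**Figure D5:**
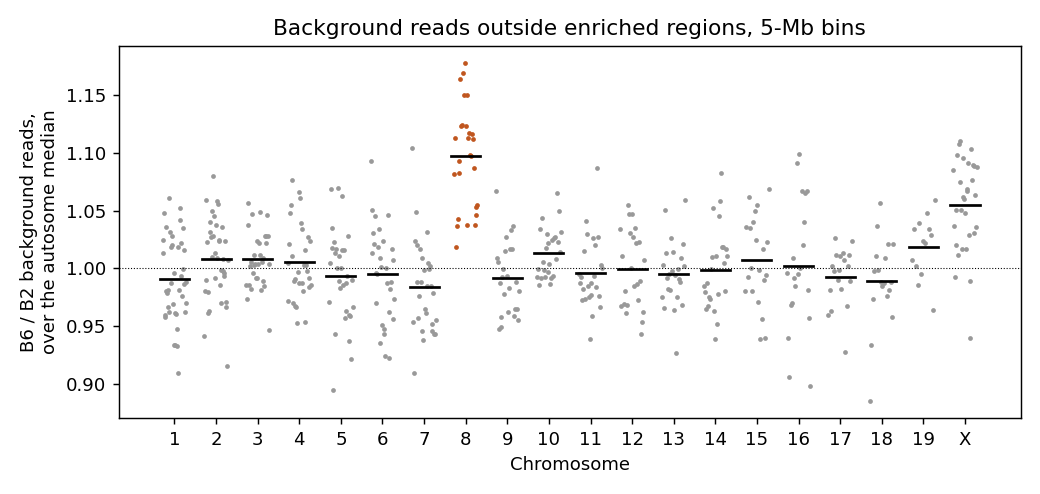
Ratio of B6 to B2 background reads over the autosomal median (vertical axis) by chromosome (horizontal axis), with 1 point per bin of 5 Mb in order along the chromosome and black bars for means. The 27 bins of chromosome 8 (orange) lie between 1.02 and 1.18.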

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

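The tests of matching positions below were all chosen after the regions had been seen. Reads with 2 alignments stood outside the main comparison and are given here because they held signal of their own. Taken alone, they gave 462 regions in both libraries, and 252 of these lay outside all regions of reads with 1 alignment. Chromosomes 3 and 17 held 28 each, and chromosome 12 held 24. Of 154 regions with at least 50 read ends in B2 within their borders, 80 formed 40 pairs in which at least 80% of ends matched at 1 constant distance, and 36 pairs lay on 1 chromosome. After ends were moved at random by up to 50 bp, at most 50.8% matched. On chromosome 12, the region 55640601 to 55641350 paired with 55650801 to 55651600, with 469 and 476 distinct reads in B2 and 213 and 214 in B6. On chromosome 13, 21817501 to 21818050 paired with 21840801 to 21841350, with 419 distinct reads in each in B2 and 190 in each in B6. On chromosome 3, 96324201 to 96325000 paired with 96331651 to 96332400 (447 and 442 in B2, 219 and 218 in B6). A read with 2 alignments is listed at both, so such counts do not tell which copy was bound.

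Reads on chromosome M also gave signal outside the main measurement, at 0.102% of reads with 1 alignment in B2 and 0.201% in B6. Among 159 regions of reads with 2 alignments and at least 50 ends, counted here with 200 bp on either side, 16 had at least 99% of ends at 1 constant distance from ends on chromosome M. That threshold was the third tried. At 50% all 159 passed and at 90% 37 passed, and neither parted the ends from randomly moved ones. Dense coverage of chromosome M could account for this, which was not tested. The largest of the 16 held clear margins: on chromosome 1 from 24567451 to 24568300, 100% matched against 69.0% after random moves, and on chromosome 2 from 22440251 to 22441450, 99.8% against 69.2%. The margin was small for the region on chromosome 7 from 111588601 to 111588850, at 100% against 95.8%.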

How the results depend on the processing

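Reads with 1 or 2 alignments, genes without receptor genes, autosomes only and counts per mapped Mb were alternatives chosen after seeing the data. Overlap of B6 with B2 regions stayed between 93.9% and 97.2% under the alternatives it was computed for, which leave out the genome-wide rate alone. The number of regions moved by more than 1.5 times in B6 at a p threshold of 1e-6 (10313) and, with the genome-wide rate alone, in B2 (24506) and B6 (13755); the other alternatives stayed within 1.5 times. The correlation across regions was 0.828 with a pseudocount of 0.1, 0.878 with a pseudocount of 2 and 0.870 in regions called in both libraries only. Differing regions numbered 924 with all reads kept, 5712 with the expected share from total distinct reads and 123 in regions called in both libraries only, where 6444 were tested. The relation of regions to genes per chromosome ranged from r = 0.879 to 0.919 with 1 library left out, and became -0.410 per mapped Mb. Without chromosomes Y and 7, r per mapped Mb was 0.832. These were left out together, and r without Y alone was not computed. Chromosome Y had 256 annotated genes on 1.205 mapped Mb and only 0.830 regions per Mb. Chromosome 7 had 2030 genes on 118.3 Mb and 3.91 regions per Mb, above the autosomal median of 3.10. These values point to Y rather than 7 as the source of the negative sign. For the other changes the cause was not tested. At matched depth, other random draws gave 2488 to 2585 regions, and thinning before removal of duplicates gave 3249. Occupancy at gene promoters and its alternatives were not run, since they need an annotation of mm8. At the depth of B6, 0% of simulated sites at 20-fold were found, against 100% at the depth of B2.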

Other observations

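The tests of tRNA and histone genes, of the distance between strands in runs and of 1 library read on 2 occasions were chosen only after the related results were seen; the tests on chromosome 8, on chromosome 17 and on the read ratio in runs were written before their values were known, but for patterns already noticed in the data.

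Relative to the other autosomes, chromosome 8 had a higher share of background reads in B6 than in B2. Once region density, reads with 2 alignments and read density were regressed out, its mean residual was 0.134 on the log2 scale, above the highest other autosome (0.0290, chromosome 19, with an SD of 0.0139 among the others), which argues against those properties as the whole cause; the residual of X was 0.0469. If the cultures were separate, more copies of chromosome 8 per cell in the B6 culture is a candidate explanation. Shared regions of chromosome 8 were also higher, by 0.143 in median log2 ratio (bootstrap interval 0.108 to 0.198, highest other autosome 0.0649). If B2 cells had the normal number, 1 extra copy in 19.2% of B6 cells would give the mean background excess over bins of 5 Mb, 0.132 on the log2 scale. The excess was uneven along the chromosome. Bins from 50000001 to 65000000 had 1.15 to 1.178 times the autosomal median, and those from 115000001 on had 1.038 to 1.055. This share of cells therefore describes only the mean, and an even gain of the whole chromosome was not shown. Read length, passages off feeders and sequencing run differ between the libraries, and GC content was not tested, so these stay open.

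The dense runs had a median ratio of B6 to B2 RPM of 1.90, against 2.01 in other shared regions. That met the bound written in advance against background. It also lay below 1.936, the 5th percentile of random sets, as written for background, but above the 1.2 that this also required. Bins of 10 kb outside regions and rich in reads with 2 alignments had a ratio of 0.877 (bootstrap interval 0.861 to 0.893). The 16 regions that matched chromosome M had a median of 2.77, though chromosome M held a larger share of reads in B6. These comparisons disagreed, so the ratio alone decided nothing. In B2 the strands were 102 bp apart in the median region of the runs, against 94 bp in other shared regions. They were farther apart than the read length of 36 in 90.5% of regions in runs. In those 16 regions the median was 32.8 bp (bootstrap interval 16.5 to 37), with 37.5% above the read length. That met the bounds set against a pile-up of unbound reads as the cause of the whole pattern. The test cannot decide this alone, because calling moved ends by 60 bp, which favours separated strands. In wide regions only the middle was measured. As an exception, the run on chromosome 9 had a median of 36 bp, so it may be such a pile-up. It is also 1 of 3 runs that hold paired regions of reads with 2 alignments. Over 21 chromosomes, regions in runs and core histone genes had rho = 0.463 (permutation p = 0.0208, adjusted p = 0.0625 over 3 relations, r = 0.966). Without chromosomes 13 and 3 rho was 0.140. Those chromosomes held 53 and 10 of the 67 core histone genes. The relation therefore rests on them, and leaving them out could not test it. The rule written for that test asked only for the unadjusted p, which was met. The stricter reading was adopted after the values were seen. For tRNA genes rho was 0.332 (permutation p = 0.142, adjusted p = 0.212, r = 0.784), without chromosomes 13 and 6 rho was 0.323 and r 0.393, and neither gene class can be placed within a run without an annotation of mm8.

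The stretch on chromosome 17 from 39451201 to 39456950 held 0.264% of all nuclear reads of B2 and 0.832% of those of B6, a ratio of 3.16, where shared regions had a median of 1.81 and a 95th percentile of 3.19. Reads of a many-copy sequence placed on 1 copy could account for it. The prediction written in advance counted a ratio at or above the shared median against this, and that bound was met. It was set aside after the counts were seen, because a many-copy sequence that TBP also binds would give a high ratio too. Among reads with 2 alignments, chromosome 16 from 18446651 to 18447000 matched 39454351 to 39454600 within the stretch at 100% of ends, so part of it has another copy and the question stays open.

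Whether both files held 1 sequencing library read on 2 occasions was also tested: the libraries shared 4044 more read ends than at 1 bp away, 1.23% of the 328322 that a single pool of molecules would give, which argues against it.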
